A study of Mus musculus with 2 samples.

How the data were processed

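Single-cell RNA sequencing was done on ventricular non-myocytes of 2 wild-type C57BL/6 mice of 10 to 12 weeks, with 1 library per mouse. Per the labels, hearts were perfused and digested, the atria were removed, myocytes were spun out at 50 g for 3 min, and the suspension was passed through a 100 µm filter. Red cells were lysed, live cells were sorted as negative for a dead-cell dye, and libraries were made with version 2 of the droplet 3' kit. The authors named FastQC (no version given) and Cell Ranger 2.2.0 with the mouse build mm10 in their processing notes. The deposited values are counts: raw UMI counts per gene symbol and cell barcode, with no normalization. A UMI is a tag that marks 1 captured RNA molecule. The rule by which the authors chose the barcodes is not stated.

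The tables held 7732 barcodes and 21355383 UMIs for mouse 1, and 6367 barcodes and 15174548 UMIs for mouse 2, over 27998 genes. Cells were kept with at least 500 UMIs, at least 300 genes and at most 10% mitochondrial UMIs, which removed 719 and 432 barcodes. Doublets were called per mouse with Scrublet as implemented in scanpy 1.11.5, which removed a further 460 and 250. The 12238 cells kept (6553 and 5685) were scaled to 10000 UMIs per cell and log-transformed after adding 1. Clustering used 2000 variable genes, 30 principal components, 15 nearest neighbours and Leiden communities at resolution 1, with no batch correction. A fixed panel of 517 genes in 21 lists, as well as sex-linked, mitochondrial and ribosomal protein genes, was left out of the clustering, so that the panel genes compared between classes did not define the classes. Of the panel, 510 genes were in the tables and the others were not analysed here. CPM means the UMIs of a gene over all UMIs of the summed cells, times 10 to the power 6. The 23 clusters were named from fixed marker genes that were not on the panel. A name ending in -like means only that at least 3 markers of that type, and at least 50% of those detected, stood at least 3-fold above the median of the other clusters at 50 CPM or more. A cluster with 80% or more of the markers of a second, unrelated type was called mixed. The marker genes were fixed beforehand, but this rule for turning them into names was written after the clusters had been looked at, including that 2 clusters carried cardiomyocyte markers. Leaving the mixed clusters out of the gene comparisons was therefore a choice made after the data were seen. The main classes were fibroblast-like, endothelial-like, mural-like (the pericyte and smooth muscle types, of which only 1 cluster, named after pericytes, was found) and macrophage-like (with monocyte and dendritic cell types). Cells of the 3 large classes were clustered again with 1000 variable genes, 20 components and resolution 0.5.

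The 21 lists of the panel, the marker genes, the tests between classes and subclusters, the call thresholds, cell filters, clustering settings and the rule for named genes were chosen before the data were examined. Lists of acute-phase, clock, heat shock and glucocorticoid genes, and the tests of explanations in the closing section, were drawn up after the mice had been compared. UMIs were summed per class and mouse and tested in edgeR 4.0.16 (R 4.3.3) with TMM scaling, the filterByExpr filter and quasi-likelihood F tests, with mouse as a replicate block because every class came from the same 2 animals. The 4 main classes shared 1 fit with 3 residual degrees of freedom, so calls rest largely on a spread shared across genes. A call needed a Benjamini-Hochberg adjusted p below 0.05 over all genes tested and an absolute log2 fold change of at least 1. A gene highest in a class had to pass against each of the other 3 classes, with the largest of the 3 p-values adjusted. Subclusters with at least 30 cells in each mouse were tested against the rest of their class in the same mouse, with 1 residual degree of freedom. Each list was also adjusted over the list alone. Errors of log2 fold changes are standard errors (SE) derived from the F statistic; errors of CPM are SD over the 2 mice (n = 2). Shares of cells carry exact Clopper-Pearson 95% intervals. The mice were compared within a class with no test, as there was 1 library on each side, over genes with at least 100 UMIs in 1 mouse. Ratios of counts carry exact binomial 95% intervals, and a count of 0 was set to 3 counts over the group for a lower bound. Intervals and floors cover counting error only.

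Named genes were the 12 called panel genes with the largest change in each direction between fibroblast-like and endothelial-like cells, with the same direction in each mouse. To these were added the 8 with the largest fold over the next class for each main class, and the 4 with the largest rise and 2 with the largest fall per subcluster. All had at least 50 CPM on the higher side in each mouse. Up to 4 further members per list were taken by CPM in the class concerned, and only those called are printed. For the mice, 5 genes in each direction were taken. A few genes that the rule selects are not used here. Marker genes are named as such. Gene positions come from GENCODE vM21 on the same build, matched by symbol.

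The tests were tried on simulated data in which 100 genes were changed at each true size (50 of them raised, for the highest class). Recovery meant an adjusted p below 0.05 in the right direction, without the fold floor of a call. False calls used the full call rule. At a true log2 change of 1 the median fitted change was 1.02 between the classes and 0.902 for the highest class. Recovery under the full call rule can therefore be lower. For fibroblast-like against endothelial-like cells, edgeR recovered 64% of genes with a true log2 change of 1 and 91% of those with 2, with 2 false calls among 11358 genes. For a highest class it recovered 10% and 52%, and for an endothelial-like subcluster 27% and 67% with 4 false calls among 8386 genes. Every simulated gene had the same spread, taken from the fit of the classes, with no difference between mice and with groups given beforehand. The real subclusters were made by clustering the same cells, so the 4 false calls do not measure the error of their calls. Alternatives covered DESeq2 1.42.0 size factors and its Wald test, no filter on low counts, no replicate block, no fold floor, all named classes in the fit, leaving out each mouse, keeping doublets, no filter on cells, other resolutions, centring within each mouse, panel genes allowed in the clustering, and splitting each cell's counts so that clusters and tests used different molecules. Python 3.11.15, anndata 0.12.19, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 were used. The mixed clusters, lymphocytes and other small classes were counted but not tested for genes, since the panel comparison was fixed on the 4 main classes.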

Results

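The data hold 12238 single cells from the ventricles of 2 mice, each an independent animal with its own library and both in 1 group of heart non-myocytes, so there is no treatment contrast. The comparisons are between cell classes within the same hearts. Median depth was 2532 UMIs per kept cell in mouse 1 and 2192 in mouse 2. Summed UMIs per class and mouse ran from 58187 (mural-like, mouse 2) to 8241753 (macrophage-like, mouse 1).

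Macrophage-like cells were the most abundant class, at 41.8% of kept cells in mouse 1 (95% interval 40.6 to 43.0) and 41.8% in mouse 2 (40.5 to 43.1), a mean of 41.8% ± 0.0083 (SD, n = 2). Fibroblast-like cells, which carry Dcn, Lum and Tcf21, made up 27.9% (26.8 to 29.0) and 23.1% (22.0 to 24.2), a mean of 25.5% ± 3.43. Endothelial-like cells, which carry Pecam1 and Cdh5, made up 17.1% (16.2 to 18.1) and 26.5% (25.4 to 27.7), a mean of 21.8% ± 6.64. Mural-like cells with the pericyte markers Rgs5, Kcnj8 and Vtn were rare, at 1.14% (75 cells) and 0.721% (41 cells). Neutrophil-like cells with S100a8 and S100a9 numbered 79 in mouse 1 (1.21%, 0.956 to 1.5002) and 2 in mouse 2 (0.0352%, 0.00426 to 0.127), and the monocyte cluster within the macrophage-like class held 66 and 4 cells. T cell-like cells made up 1.88% and 1.58%, and proliferating cells with Mki67 and Top2a 1.16% and 1.64%. B, NK, innate lymphoid and lymphatic endothelial types each stayed below 1% in both mice. Mixed clusters took 6.75% in mouse 1 and 1.97% in mouse 2. Among them, a cluster of macrophage type that also carried cardiomyocyte markers held 5.74% and 1.65%. It was left out of the macrophage-like share by a rule written after the clusters had been looked at. The near-equal macrophage-like shares depend on that choice. No test was run between the mice, and shares follow digestion, spins and the live-cell sort as well as the tissue.

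**Figure D1:**
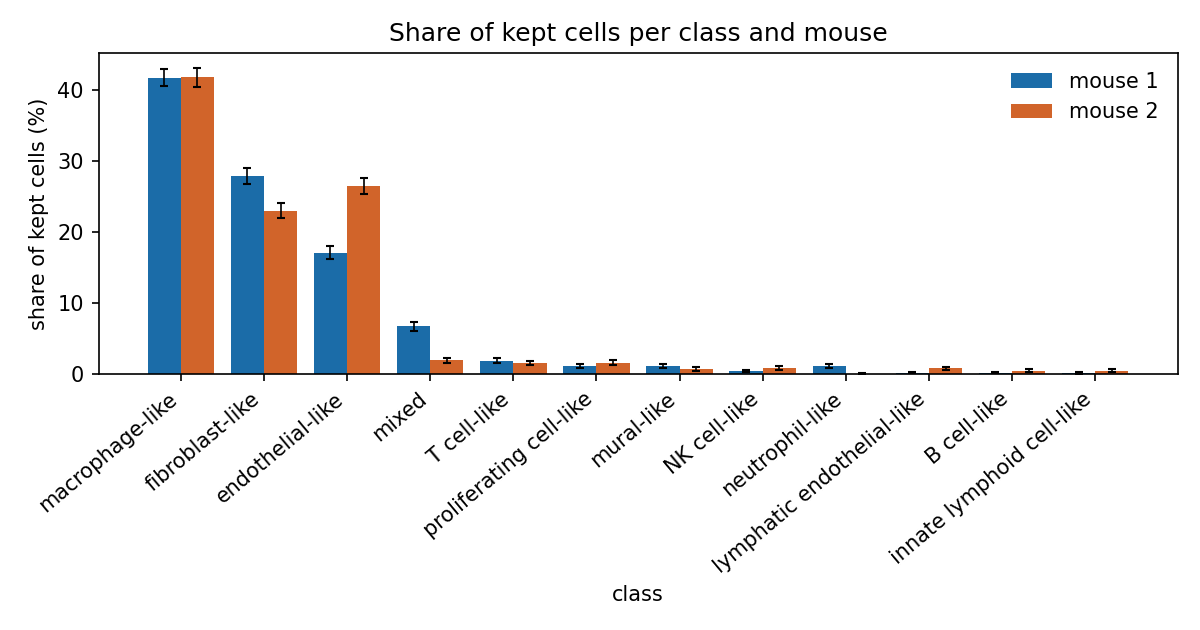
Share of kept cells (%, vertical axis) in each class (horizontal axis) for mouse 1 and mouse 2; error bars are exact 95% binomial intervals of each mouse. Macrophage-like cells, without the mixed cluster of macrophage type, took 41.8% in both mice, while endothelial-like cells took 17.1% and 26.5%.

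Fibroblast-like and endothelial-like cells differed in most of the fixed panel. Fibroblast-like cells were higher in genes of fibrillar collagen, with Col1a1 and Col1a2, the chains of type I collagen, at 636 ± 112 and 916 ± 50.2 CPM against 6.11 ± 0.299 and 9.64 ± 0.522 CPM in endothelial-like cells (SD, n = 2 mice). They were also higher in Pdgfra, a receptor for platelet-derived growth factor, and in the chemokine Cxcl14 at 1292 ± 367 against 12.0 ± 6.18 CPM. Endothelial-like cells were higher in Sox18 and Sox17, transcription factors of vascular development, and in Fabp4, a fatty acid-binding protein, which reached 23139 ± 1264 CPM against 218 ± 31.5 CPM. The test called 291 of 457 panel genes, 160 higher in fibroblast-like and 131 higher in endothelial-like cells. Over all 11730 genes tested, 1897 were called higher in fibroblast-like and 1661 higher in endothelial-like cells.

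Among the genes with the largest changes toward fibroblast-like cells, log2 fold changes (± SE) were 6.85 ± 0.21 for Cxcl14, 6.80 ± 0.28 for the matrix protease Mmp3, 6.78 ± 0.29 for the Wnt antagonist Sfrp1, 6.74 ± 0.23 for Col1a1 and 6.66 ± 0.30 for Pdgfra. They were 6.62 ± 0.21 for Col1a2, 6.61 ± 0.23 for fibulin-1 (Fbln1), 6.56 ± 0.20 for the C1 inhibitor Serping1 and 6.37 ± 0.37 for the mesenchymal transcription factor Prrx1. The mice differed for Pdgfra, with a log2 ratio of 8.28 over 1 endothelial-like UMI in mouse 1 and 5.87 over 9 in mouse 2. For 3 more genes the endothelial-like side held only 2 or 3 UMIs, so the ratio of pooled counts is given. Bmper, a BMP-binding protein, was higher by 138-fold (95% interval 38.0 to 1143), the Wnt antagonist Sfrp2 by 116-fold (95% interval 39.4 to 562) and Sox9 by 101-fold (95% interval 34.5 to 493). Toward endothelial-like cells, the log2 fold change of fibroblast-like over endothelial-like was -8.39 ± 0.28 for Sox18, -7.91 ± 0.24 for the adhesion molecule Icam2, -7.60 ± 0.28 for the glycerol channel Aqp7, -7.28 ± 0.30 for Gata2, -7.22 ± 0.30 for Ramp3, -7.10 ± 0.26 for the apelin receptor Aplnr and -6.98 ± 0.26 for Itga6. It was -6.86 ± 0.38 for Sox17, -6.81 ± 0.24 for Egfl7, -6.76 ± 0.33 for Pparg and -6.69 ± 0.45 for Fabp4. Tnfsf10, the death ligand TRAIL, was 173-fold (95% interval 58.5 to 844) higher in endothelial-like cells over 3 UMIs in fibroblast-like cells. Among these 24 genes the largest adjusted p was 3.4e-04, for Fabp4, and all 24 had the same direction in both mice by the rule that chose them. On mm10, Col1a1 lies on chromosome 11, 94936224 to 94953042, Sox18 on chromosome 2, 181669836 to 181671640, and Fabp4 on chromosome 3, 10204088 to 10208576.

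By list, 20 of 23 tested fibrillar matrix genes were higher in fibroblast-like cells and 0 in endothelial-like cells, among them Bgn (log2 3.88 ± 0.16), Pcolce (4.92 ± 0.17) and Col3a1 (6.34 ± 0.22). Basement membrane genes split 8 to 2 of 17 tested, with Nid1 (2.67 ± 0.16) and Lamc1 (3.15 ± 0.16) on the fibroblast-like side. Matrix proteases and their inhibitors split 15 to 6 of 23, with Timp2 (3.42 ± 0.17) and Mmp2 (5.79 ± 0.21) against Timp4 (-6.54 ± 0.20). In the Wnt list 13 of 20 were higher in fibroblast-like and 3 in endothelial-like cells. TGF-beta and BMP genes split 17 to 7 of 29, where Fstl1 (3.72 ± 0.17) was higher in fibroblast-like cells and Id1 (-5.81 ± 0.20) and Eng (-2.59 ± 0.16) in endothelial-like cells. Fatty acid and lipoprotein handling went 4 to 12 of 22, with the fatty acid transporter Cd36 (-6.35 ± 0.49) and Gpihbp1 (-6.64 ± 0.60), which carries lipoprotein lipase, on the endothelial-like side. Interferon-stimulated genes went 1 to 17 of 24, with Isg15 (-2.22 ± 0.16) and Bst2 (-1.96 ± 0.16) higher in endothelial-like cells and Ifi27l2a (2.91 ± 0.16) in fibroblast-like cells. Growth factor receptors went 5 to 12 of 20, with the VEGF receptors Kdr (-5.98 ± 0.21) and Flt1 (-6.60 ± 0.52) endothelial-like, and Notch genes 3 to 7 of 14, with Notch1 (-3.28 ± 0.20) endothelial-like.

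Among the other lists, growth factors split 14 to 10 of 29, cardiac and vascular transcription factors 11 to 15 of 31, vasoactive signalling 7 to 7 of 22, and adhesion molecules and integrins 7 to 7 of 29. Chemokines split 8 to 5 of 22, with Ccl7 (3.97 ± 0.19) fibroblast-like and Cxcl12 (-3.42 ± 0.16) endothelial-like. Complement split 8 to 3 of 18, with C3 (5.84 ± 0.19) against Cd93 (-6.34 ± 0.34). Antigen presentation went 1 to 6 of 20, with B2m (-1.42 ± 0.18) and H2-K1 (-1.46 ± 0.15) higher in endothelial-like cells. Chemokine receptors split 3 to 1 of 10, cytokines 4 to 4 of 15, cytokine receptors 4 to 1 of 24, phagocytosis and scavenging 5 to 1 of 21, and immediate early and heat shock genes 3 to 5 of 25. Adjusted over the list alone, the counts were the same in each of these 21 lists except for 18 rather than 17 TGF-beta and BMP genes higher in fibroblast-like cells. Free RNA may limit these folds: in mouse 1 the 10 fibroblast markers used for naming stood in endothelial-like cells at 0.663% to 4.97% of their fibroblast-like CPM. Whether these marker counts were free RNA was not tested.

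**Figure D2:**
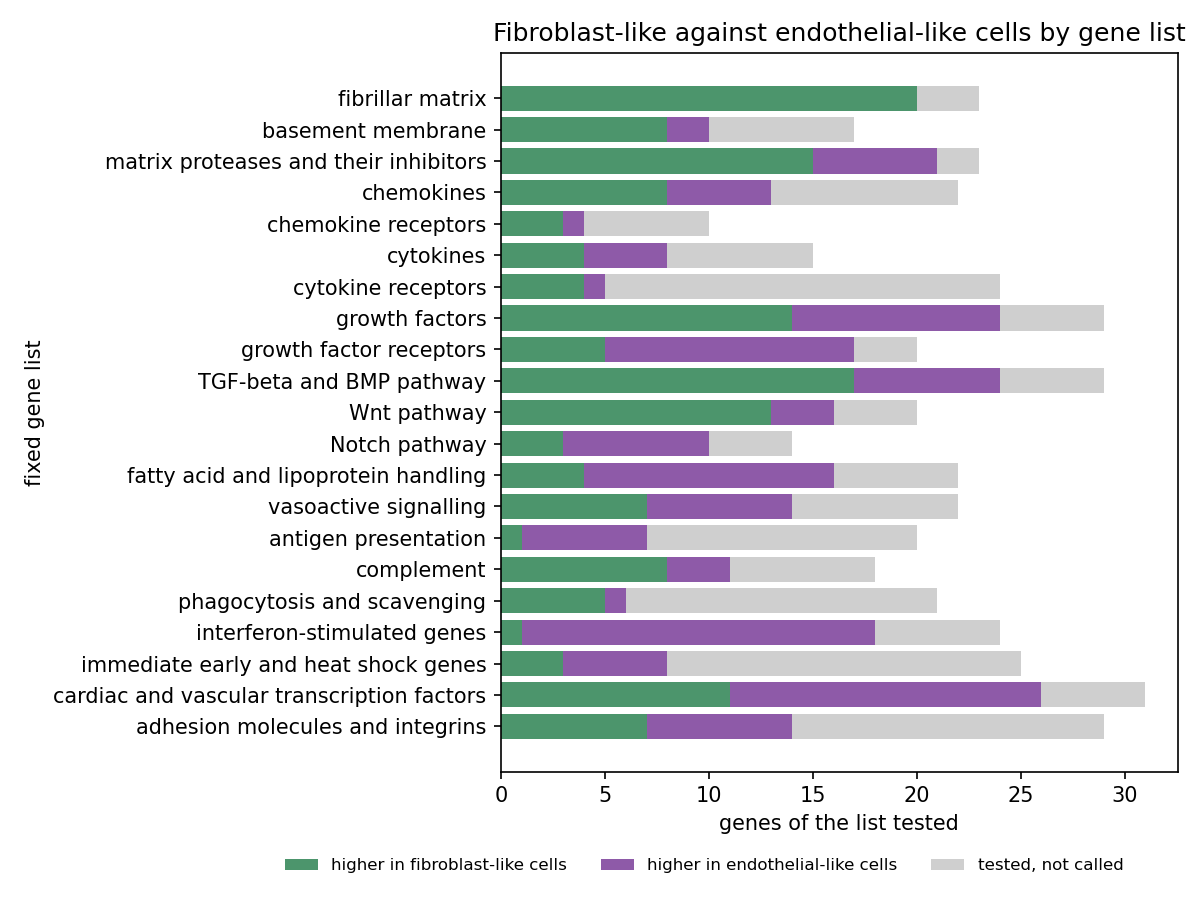
Number of tested genes (horizontal axis) in each of the 21 fixed lists (vertical axis) that were called higher in fibroblast-like cells, called higher in endothelial-like cells, or not called by edgeR over both mice. Fibrillar matrix had 20 genes higher in fibroblast-like cells, and interferon-stimulated genes had 17 higher in endothelial-like cells.

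Genes highest in fibroblast-like cells over all 3 other main classes numbered 69 panel genes. Over the next class, Cxcl14 had a log2 fold change of 5.99 ± 0.18 (SE), Mmp3 5.75 ± 0.21, the complement component C3 5.17 ± 0.17, Fbln1 5.01 ± 0.33 and the collagen Col8a1 4.72 ± 0.22. C3 stood at 1246 ± 835 CPM (SD, n = 2). For Frzb the next class by the fit was endothelial-like, which held 3 UMIs, and the ratio was 78.4-fold (95% interval 26.7 to 381). For Pdgfra it was 44.7-fold (95% interval 8.02 to 1768) over 1 UMI in mural-like cells, and for Sfrp1 18.3-fold (95% interval 6.25 to 88.7) over 3. Mural-like cells held 0 UMIs of Frzb and Mmp3, but only 134259 and 58187 UMIs in all in the 2 mice. The folds of Frzb and Mmp3 therefore do not bound those over mural-like cells, which may be smaller. By list, 18 of 23 fibrillar matrix genes (19 adjusted over the list alone), 9 of 29 TGF-beta and BMP genes (9), 8 of 23 matrix proteases and inhibitors (11), 5 of 17 basement membrane genes (6), 5 of 18 complement genes (5), 4 of 22 chemokines (4) and 3 of 20 Wnt genes (3) were highest here. Frzb lies on chromosome 2, 80411970 to 80447625.

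Endothelial-like cells were the highest class for 47 panel genes. Aplnr led with 5.51 ± 0.21 at 219.8 ± 102 CPM against 3.47 ± 0.955 CPM in macrophage-like cells, the next class by the fit. Mural-like cells, the main class with the fewest UMIs, held 0 UMIs of Aplnr, so its fold over them may be smaller. Icam2 followed with 3.53 ± 0.30, the protease inhibitor Timp4 with 3.46 ± 0.25, the junction protein Jam2 with 3.43 ± 0.17 and the antiviral gene Rsad2 with 3.07 ± 0.42. Mural-like cells held 2 UMIs each of Sox7, Bcl6b and Nos3, the endothelial nitric oxide synthase, which gave ratios of 11.4-fold (95% interval 3.14 to 94.4), 8.43-fold (95% interval 2.32 to 69.8) and 8.20-fold (95% interval 2.25 to 68.0). Highest here were 6 of 20 growth factor receptors (6 adjusted over the list alone), 6 of 22 genes of fatty acid handling (9), 6 of 24 interferon-stimulated genes (9), 5 of 31 transcription factors (6) and 4 of 22 vasoactive genes (4). Aplnr lies on chromosome 2, 85136225 to 85139923.

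Mural-like cells were highest for 15 panel genes, 6 of which belong to vasoactive signalling (6 of 22 tested, and 6 adjusted over the list alone). Both subunits of soluble guanylate cyclase, the receptor for nitric oxide, were among them, with Gucy1b3 at 647 ± 252 CPM (log2 4.80 ± 0.27 over fibroblast-like cells) and Gucy1a3 at 500.1 ± 51.1 CPM (5.07 ± 0.32). The receptors Ednra for endothelin (6.41 ± 0.70) and Agtr1a for angiotensin II (4.12 ± 0.89), Notch3 (5.71 ± 0.38), the integrin Itga7 (5.68 ± 0.60) and Il34 (4.90 ± 0.50), a ligand of the macrophage receptor Csf1r, were also highest here. The class held 116 cells, and Agtr1a rested on 7 and 3 UMIs in the 2 mice. Notch3 lies on chromosome 17, 32120820 to 32166852.

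Macrophage-like cells were highest for 77 panel genes. Cd74, the invariant chain of class II antigen presentation, reached 20098 ± 5269.7 CPM (6.39 ± 0.16 over endothelial-like cells). C1qa and C1qb, the opening components of the classical complement pathway, reached 7839 ± 572 and 7153 ± 774 CPM (5.82 ± 0.17 and 5.63 ± 0.17). C1qa stood at 135 ± 27.9 CPM in fibroblast-like, 189 ± 34.0 in endothelial-like and 188 ± 71.3 in mural-like cells. Whether these lower values were free macrophage RNA was not tested, so free RNA may limit the folds of this class too. The complement receptors C5ar1 (6.10 ± 0.19) and C3ar1 (6.01 ± 0.21), the Fc receptor Fcgr3 (5.92 ± 0.19), the chemokine receptor Ccr1 (5.80 ± 0.28) and the protease Ctss (5.62 ± 0.18) made up the rest of the named genes. Mural-like cells, the main class with the fewest UMIs, held 0 UMIs of C3ar1 and Ccr1, so the folds of these genes over them may be smaller. By list, 19 of 21 phagocytosis and scavenging genes (19 adjusted over the list alone), 9 of 20 antigen presentation genes (10), 9 of 22 chemokines (11), 7 of 18 complement genes (7) and 7 of 24 cytokine receptors (10) were highest here. Cd74 lies on chromosome 18, 60803848 to 60812652.

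**Figure D3:**
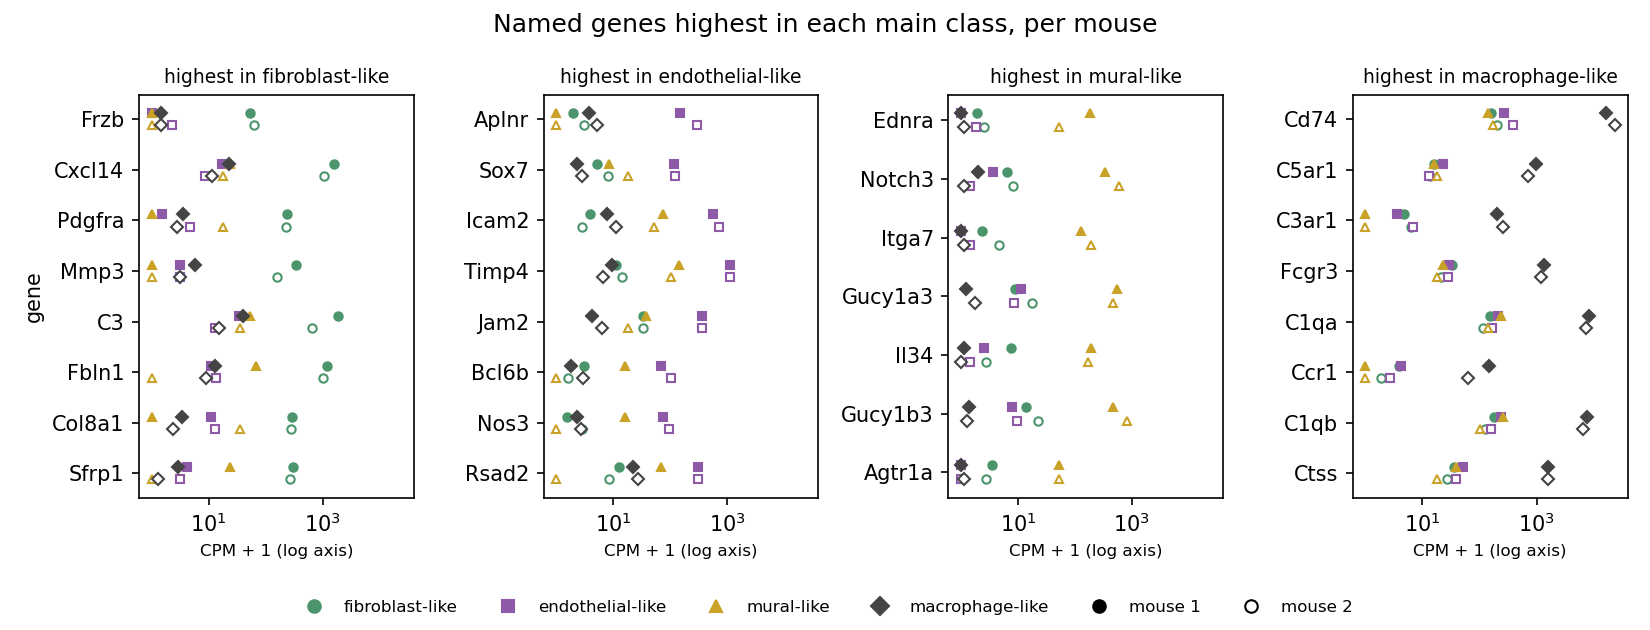
CPM plus 1 (horizontal log axis) of the named genes (vertical axis) highest in each of the 4 main classes, 7 for mural-like cells and 8 for the others; symbols mark the class, filled for mouse 1 and open for mouse 2. In each panel both mice show the named class on the right, as for Cd74 at 20098 ± 5269.7 CPM in macrophage-like cells.

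Within the fibroblast-like class, 3 of 7 subclusters had 30 cells in each mouse, and 96 panel genes were called in at least 1 of them. Subcluster 3, with the adventitial markers Pi16, Cd248 and Ly6a, held 8.42% and 8.70% of the class in the 2 mice. It was higher in Fn1, fibronectin (2.22 ± 0.18; 172 ± 38.9 against 36.9 ± 5.33 CPM), Thy1 (2.19 ± 0.21), the complement regulator Cd55 (2.12 ± 0.12) and the chemokine scavenger Ackr3 (2.02 ± 0.11). It was lower in the vasodilator peptide Adm (-3.77 ± 0.23) and the chemokine Ccl19 (-3.05 ± 0.31). In that subcluster 4 of 6 chemokine receptors were higher (4 adjusted over the list alone), and growth factors split into 4 higher and 7 lower of 21 (4 and 9). Subcluster 4 held 119 and 40 cells. Its named panel gene with the largest rise was the matrix protein Postn (4.74 ± 0.24, at 257 ± 197 against 10.5 ± 1.58 CPM). Postn rested on 158 UMIs in mouse 1 and 14 in mouse 2. Ctgf (2.19 ± 0.17), Col8a1 (1.60 ± 0.12) and Ackr4 (1.52 ± 0.24) were also higher. Of 17 chemokines 5 were lower there (5 adjusted over the list alone), among them Cxcl14 (-2.38 ± 0.12) and Ccl11 (-2.34 ± 0.22), and 4 of 23 fibrillar matrix genes were higher and 1 lower (4 and 1). Subcluster 1 came almost wholly from mouse 2 (81 and 1068 cells), with Adm (1.31 ± 0.15), Fabp5 (1.12 ± 0.26), Frzb (1.09 ± 0.27) and Thbs2 (1.07 ± 0.22) higher and Ccl2 (-3.01 ± 0.15) and Fn1 (-1.94 ± 0.27) lower. The rest it was tested against differed between the mice, with 1133 and 23 cells of subcluster 0 and 154 and 114 of subcluster 3. Ccl2 was among the leading genes of subcluster 0. In mouse 2, subcluster 3 held 57 of the 82 Fn1 UMIs of the rest. These changes may therefore reflect the rest as well as subcluster 1. The count of 96 was 55 with DESeq2, 41 with no replicate block and 161 with no fold floor.

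Endothelial-like cells separated into 5 tested subclusters with 196 panel genes called. Subcluster 3, with the endocardial markers Npr3, Cytl1 and Vwf, held 7.04% and 6.77% of the class and 149 of the calls, 80 higher and 69 lower. Fst and Nrg1, which encode follistatin and neuregulin 1, were at 0 UMIs in the rest of the class and were at least 219.6-fold and at least 135-fold higher in it (floor of 3 UMIs over the group), while Inhba, a subunit of activin, was 221-fold (95% interval 57.9 to 1879.9) higher and Timp1 132-fold (95% interval 33.2 to 1142). Tbx3 and Mmp15 were at 0 UMIs in that subcluster and at least 12.1-fold and at least 7.26-fold lower. TGF-beta and BMP genes were higher in 15 of 25 and lower in 1 (15 and 1 adjusted over the list alone). Genes of fatty acid and lipoprotein handling were lower in 11 of 17 and higher in 3 (11 and 3), with Fabp4 at -2.76 ± 0.14, Cd36 at -3.20 ± 0.16, Gpihbp1 at -4.56 ± 0.19 and Lpl at -3.70 ± 0.20. Fibrillar matrix genes were higher in 9 of 17 and lower in 3 (11 and 3).

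Subcluster 4, with the arterial markers Gja5, Gja4 and Sema3g, was higher in Col18a1 (3.39 ± 0.61), Col8a1 (2.95 ± 0.66), the vasoconstrictor Edn1 (2.91 ± 0.32) and Ace (2.81 ± 0.50). Aplnr was at 0 UMIs in it and at least 16.9-fold lower, and Nrp2 33.0-fold (95% interval 9.12 to 273) lower. Subcluster 1, which had 3 of 7 capillary markers and stayed unnamed, was higher in the Notch target Hey1 (2.15 ± 0.16), the Notch ligand Dll4 (1.09 ± 0.16), Cxcl12 (1.41 ± 0.07) and Aqp7 (1.297 ± 0.10), and lower in Vcam1 (-4.14 ± 0.18). Subcluster 2, which had 2 of 6 venous markers and stayed unnamed, was higher in Cxcl10 (4.94 ± 0.32), Pdgfa (2.37 ± 0.21), Insr (2.05 ± 0.27) and the venous transcription factor Nr2f2 (1.97 ± 0.18), and lower in Hey1 (-3.19 ± 0.31). Its venous markers, Lrg1 and Tmem252, were both higher in mouse 1 over the endothelial-like cells. The rise of Pdgfa differed between the mice, at 284 against 36.9 CPM in mouse 1 and 63.5 against 24.3 CPM in mouse 2. In subcluster 2, 6 of 23 interferon-stimulated genes were higher and 0 lower (6 and 0 adjusted over the list alone). Subcluster 0 was higher in Adm (1.76 ± 0.23), Cxcl9 (1.33 ± 0.15), Bcl6b (1.16 ± 0.17) and Aplnr (1.15 ± 0.11) and lower in Clu (-5.05 ± 0.30) and Fn1 (-3.75 ± 0.37). The count of 196 was 127 with DESeq2 and 122 when clusters and tests used different molecules of each cell.

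Macrophage-like cells gave 120 called panel genes over 6 tested subclusters. In subcluster 5, 57 and 31 cells, 18 of 23 interferon-stimulated genes were higher and 0 lower (18 and 0 adjusted over the list alone), led by Ifit2 (6.82 ± 0.43), Rsad2 (5.46 ± 0.21), Ifit3 (5.35 ± 0.18) and Ifit1 (5.24 ± 0.19); Ifit3 reached 1156 ± 307 against 26.1 ± 1.13 CPM. Ifngr1 (-1.15 ± 0.24) and Pros1 (-1.41 ± 0.43) were lower there. Leaving the list out of the clustering does not make its count an independent test, since genes that vary along with it could form the subcluster. Cmpk2 and Phf11d, which are not on the panel, were among the leading genes of subcluster 5. Subcluster 4, which carried Cd209a and Klrd1, 2 of 8 dendritic cell markers, and stayed unnamed, was higher in Ccr2, the receptor by which monocytes enter tissue (3.63 ± 0.14; 754 ± 66.2 against 62.7 ± 8.53 CPM), Fn1 (4.47 ± 0.54), the integrin Itgax (4.13 ± 0.35) and Lpl (2.60 ± 0.16), and lower in Ccl24 (-4.02 ± 0.20) and Ednrb (26.5-fold (95% interval 7.32 to 219)). The rise of Fn1 differed between the mice, at 249 against 18.8 CPM in mouse 1 and 147 against 1.15 CPM (7 UMIs) in mouse 2. Antigen presentation genes were higher in 8 of 20 in subcluster 4 and lower in 0 (8 and 0), higher in 6 and lower in 1 in subcluster 1 (6 and 1), and lower in 8 and higher in 0 in subcluster 0 (8 and 0).

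Subcluster 1 was also higher in the cytokine Il1b (3.07 ± 0.11), the fractalkine receptor Cx3cr1 (1.97 ± 0.11), Tgfbr1 (1.91 ± 0.13) and Cxcl2 (1.78 ± 0.09), and lower in Ednrb (-4.40 ± 0.28) and Fgfr1 (-3.00 ± 0.19). Subcluster 3 was higher in Notch2 (2.22 ± 0.09) and lower in Ccr2 (-2.04 ± 0.16) and Il1b (-1.54 ± 0.18). Subclusters 0 and 2, which held 1460 and 85 cells of mouse 1 and 123 and 1042 of mouse 2, were both lower in Ccr2 (-3.75 ± 0.22 and -3.25 ± 0.24); subcluster 0 was higher in Ednrb (1.297 ± 0.22) and lower in Il1b (-2.20 ± 0.26), and subcluster 2 was lower in Isg15 (-1.08 ± 0.20). Subclusters 0 and 2 came mostly from different mice, so the rest that each was tested against also differed between the mice. The count of 120 was 79 with no replicate block and 193 with no fold floor.

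The 2 mice differed within every large class in acute-phase genes, which respond to inflammation; the list of these genes was drawn up after the mice had been compared. In fibroblast-like cells, mouse 1 was higher in Mt2, a metal-binding protein, by 23.01-fold (21.01 to 25.3), in Serpina3f by 18.5-fold (8.83 to 46.7), in Plac8 by 13.9-fold (6.21 to 38.5) and in the neutrophil genes S100a8 and S100a9 by 42.4-fold (16.4 to 157) and 43.9-fold (14.8 to 214) (ratios of CPM with 95% counting intervals). S100a8, S100a9 and Retnlg are neutrophil markers and Plac8 and Chil3 monocyte markers, of cells that were themselves more numerous in mouse 1, so free RNA is not excluded for these 5 genes in any class. The same holds for Hp and Lrg1 in macrophage-like cells and Hp, Lrg1 and Lcn2 in fibroblast-like cells, since these 3 genes were among the leading genes of the neutrophil cluster. Retnla was among the leading genes of macrophage-like subcluster 4, so free macrophage RNA is not excluded for it. Mouse 2 was higher in the clock gene Nr1d1 by 16.1-fold (10.4 to 26.2), in Mycn by 7.46-fold (4.72 to 12.3), in Cbfa2t3 by 4.31-fold (3.00 to 6.29), in Retnla by 3.86-fold (2.80 to 5.39) and in Gm14964 by 3.69-fold (2.77 to 4.97). In endothelial-like cells Lcn2, which binds bacterial iron carriers, had 210 UMIs in mouse 1 and 0 in mouse 2, at least 87.5-fold higher. Lrg1 was higher in mouse 1 by 11.02-fold (7.87 to 15.8), Tmem252 by 33.1-fold (14.9 to 91.6), S100a8 by 31.8-fold (13.3 to 99.5) and Mt2 by 16.0-fold (8.13 to 35.8). The Mt2 excess of mouse 1 here was 1.79% of that in fibroblast-like cells, where fibroblast markers stood at up to 4.97%. Free fibroblast RNA is therefore not excluded for Mt2 in endothelial-like cells. Mouse 2 was higher in the growth factor Vegfc by 2.77-fold (2.07 to 3.76), Ppp1r16b by 2.44-fold (1.99 to 3.01), Hhex by 2.40-fold (1.67 to 3.52), Dll1 by 2.29-fold (1.64 to 3.23) and Dok4 by 2.18-fold (1.71 to 2.79).

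In macrophage-like cells mouse 1 was higher in Saa3 by 127-fold (22.4 to 5031), Chil3 by 63.8-fold (27.1 to 197), Retnlg by 44.3-fold (12.0 to 370.3), F10 by 40.7-fold (10.996 to 341) and Hp, haptoglobin, by 38.6-fold (19.4 to 90.0). Mouse 2 was higher in the matrix proteases Mmp13 by 5.55-fold (4.08 to 7.68) and Mmp9 by 5.50-fold (3.47 to 9.06), in the iron exporter Slc40a1 by 4.01-fold (3.42 to 4.71), in Pla2g2d by 3.89-fold (3.26 to 4.67) and in Hpgd by 3.63-fold (3.37 to 3.91). Slc40a1, Pla2g2d and Hpgd were among the leading genes of macrophage-like subcluster 2 (85 and 1042 cells), and Nr1d1, Mycn and Gm14964 of fibroblast-like subcluster 1 (81 and 1068 cells), so these differences and the mix of subclusters in each mouse cannot be separated. The same limit holds toward mouse 1. Saa3, Mt2 and Lcn2 were among the leading genes of fibroblast-like subcluster 0 (1133 and 23 cells), and Mt2 and C4b of macrophage-like subcluster 0 (1460 and 123 cells). The monocyte cluster carried part of the differences for some of these genes. Without it, in a comparison added after the data were seen, the ratio of mouse 1 over mouse 2 was 1.62-fold (0.435 to 7.36) for Chil3, 5.54-fold (2.34 to 16.0) for Hp, 10.95-fold (2.75 to 95.03) for F10 and 44.6-fold (7.68 to 1794) for Saa3. The neutrophil marker Retnlg stayed at 44.6-fold (12.1 to 373), so the monocyte cluster did not carry its difference. Genes at least 2-fold apart numbered 194 of 5864 in fibroblast-like cells (133 higher in mouse 1), 75 of 3658 in endothelial-like cells (68) and 166 of 6465 in macrophage-like cells (105). Among the fixed lists, the median log2 ratio of mouse 2 over mouse 1 of the chemokines was -1.12 in fibroblast-like cells (13 of 13 higher in mouse 1), -0.96 in endothelial-like cells (5 of 8) and -0.41 in macrophage-like cells (12 of 18). Complement genes had medians of -0.42, -0.37 and -0.32, higher in mouse 1 for 9 of 10, 6 of 7 and 11 of 12. Across genes, Pearson's r of log2 CPM plus 1 between the mice was 0.957, 0.957 and 0.969; genes are not independent replicates. With 1 library per mouse, animal and library cannot be separated. Cardiomyocyte markers such as Tnnt2 and Ckm also took a larger share of UMIs in mouse 1, at 0.0328% against 0.0181% in fibroblast-like, 0.0769% against 0.0365% in endothelial-like and 0.0402% against 0.0236% in macrophage-like cells. Mt2 lies on chromosome 8, 94172664 to 94173568, and Lcn2 on chromosome 2, 32384633 to 32388252.

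**Figure D4:**
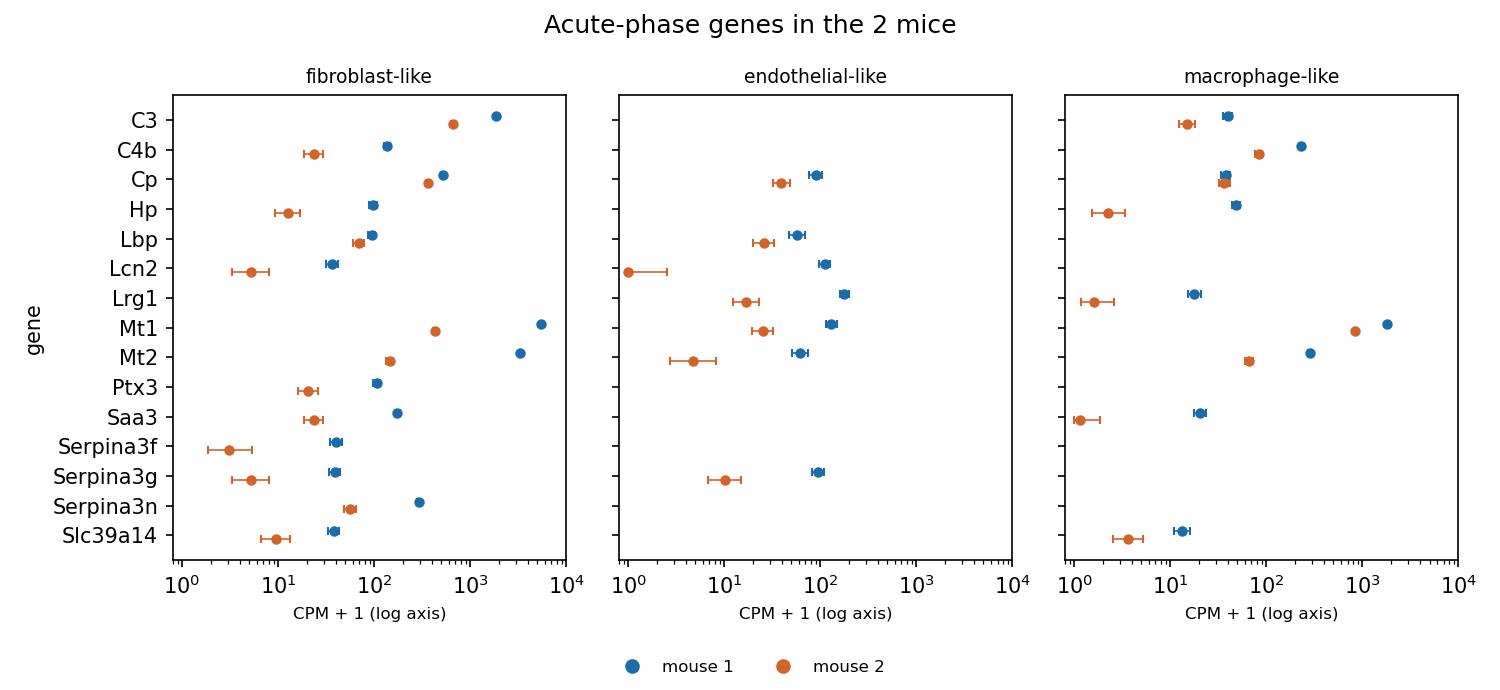
CPM plus 1 (horizontal log axis) of acute-phase genes (vertical axis; list drawn up after the mice had been compared) with at least 100 UMIs in the class in 1 mouse, in 3 classes, for mouse 1 and mouse 2; bars are 95% Poisson intervals. Mouse 1 lies to the right of mouse 2 for 14 of 14 genes in fibroblast-like, 7 of 7 in endothelial-like and 9 of 9 in macrophage-like cells.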

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

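Of the tests in this part, the comparison of median UMIs was chosen only after the result was seen, and so was the rule that called these clusters mixed. The test on variation between cells replaced one on the share of marker UMIs, whose outcome was fixed because the clusters were picked by that share. Transcripts of contractile cardiomyocyte genes (such as Myh6, Tnnt2 and Mb) appeared in clusters that the comparisons of genes did not use, although the preparation spun out myocytes. A cluster of macrophage type that carried them held 5.74% of kept cells in mouse 1 and 1.65% in mouse 2. A cluster that carried them together with fibroblast genes held 0.702% and 0.0880%. Barcodes left out for more than 10% mitochondrial UMIs had 0.504% of their UMIs in the cardiomyocyte markers in mouse 1 and 0.238% in mouse 2, against 0.0853% and 0.0338% in kept cells. They were also found in the classes compared, as in endothelial-like cells (0.0769% and 0.0365%) and mural-like cells (0.107% and 0.0344%).

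For the macrophage-type cluster 2 technical explanations were tested. Doublets of an intact cardiomyocyte and a macrophage would hold more RNA, but median UMIs of the cluster were at most 1.00 times those of macrophage-like cells in the same mouse (0.944 in the other mouse), which argues against intact cells among the kept cells of the cluster. Barcodes over 10% mitochondrial UMIs and called doublets (median 4562 and 4165 UMIs) had been removed before, so the test does not cover doublets of intact cardiomyocytes among those. Free cardiomyocyte RNA spread evenly over droplets would vary from cell to cell about as fibroblast and endothelial markers do. Its squared variation beyond Poisson noise was at least 6.23 times theirs (8.42 times in the other mouse). However, the cells compared included the cluster rich in cardiomyocyte markers. Cells rich in fibroblast or endothelial markers could have been removed as called doublets or placed in other clusters. The choice of cells may therefore have raised the ratio, and the test does not decide on an even spread. Fragments of cardiomyocytes in the same droplets, or taken up by the cells, stay open and were not tested. No biological explanation was tested, as both mice are in 1 group.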

How the results depend on the processing

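All alternatives were planned except leaving out the monocyte cluster, which was chosen after seeing the data. The 291 genes between fibroblast-like and endothelial-like cells ranged from 277 (no replicate block) to 345 (no fold floor), with 277 to 285 when 1 mouse was left out. Counts of genes highest in a class stayed within 1.5 times under every alternative run. For subclusters, no fold floor gave 161 for fibroblast-like and 193 for macrophage-like cells; more genes pass by construction. DESeq2 gave 55 for fibroblast-like and 127 for endothelial-like cells, no replicate block gave 41 for fibroblast-like and 79 for macrophage-like cells, and count splitting gave 122 for endothelial-like cells; the cause was not tested for DESeq2 and the block, and splitting leaves 50% of the UMIs. The macrophage-like share, whose SD of 0.0083 is small, moved from 41.8% to 39.4% with doublets kept, 38.8% with no filter on cells, 42.1% at resolution 0.5, 41.5% at resolution 2 and 41.6% with panel genes in the clustering. No alternative was run with the mixed cluster of macrophage type (5.74% and 1.65% of kept cells) counted in this class. The other 3 main shares moved by less than their SD. For leaving out 1 of the 2 mice this was fixed beforehand, as it always moves the mean by less than the SD. Counts of genes 2-fold apart between the mice stayed within 1.5 times, and were 157 in macrophage-like cells without the monocyte cluster. For named genes, 130 in the alternatives of the test and 54 to 56 in those that cluster anew or fit all named classes, where subcluster genes were not compared, 1244 of 1300 values kept direction and call, 56 kept direction but not the call (25 of them with no replicate block and 16 with DESeq2), and 0 reversed. Without 1 mouse there was no test, and a gene counted as kept at a log2 fold change of 1. Some of these outcomes were fixed beforehand. All 130 values with no fold floor had to be kept, since dropping a floor takes no call away. Leaving out 1 mouse could not reverse the genes named between fibroblast-like and endothelial-like cells, which were chosen for the same direction in each mouse. Depth limits the mural-like class most, at 134259 and 58187 UMIs.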

Other observations

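The tests on fibroblast RNA, stress and time of day below were chosen only after the results were seen, as were the list of acute-phase genes and the genes named in the next paragraph; those on neutrophil RNA and on unseen glucocorticoid targets were set before their values were seen. The first 3 were also revised after a first run: fibroblast RNA was first judged by the median over 14 genes, stress by immediate early genes without heat shock genes, and time of day by 1 rule over all 3 classes and then with a floor of 100 UMIs.

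Beyond the named genes, the mice differed in other fixed lists. In fibroblast-like cells the cardiac and vascular transcription factors were higher in mouse 2 for 15 of 16 genes (median log2 ratio of mouse 2 over mouse 1 0.50, quartiles 0.30 and 0.66), and interferon-stimulated genes higher in mouse 1 for 16 of 17 (median -0.44), whereas in endothelial-like cells interferon-stimulated genes were higher in mouse 2 for 16 of 21 (median 0.20); the difference between the classes was not tested. In macrophage-like cells antigen presentation genes were higher in mouse 2 for 17 of 19 (median 0.36), and phagocytosis and scavenging genes higher in mouse 1 for 17 of 20 (median -0.25). Fibroblast-like subcluster 0, with 1133 cells in mouse 1 and 23 in mouse 2, was led by Saa3, Mt2, Mt1 and Ccl2 and had too few cells in mouse 2 for a test. Fibroblast-like subcluster 2 (292 and 28 cells) and macrophage-like subcluster 3 (405 and 402 cells) shared Slc39a1, Notch2, Rpgrip1 and Actb among their 10 leading genes. Sex-linked genes gave the same picture in both mice, with Ddx3y at 82.6 and 73.4 CPM in fibroblast-like cells and Xist at 1 and 0 UMIs.

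Acute-phase genes were higher in mouse 1 in 14 of 14 genes of fibroblast-like cells (median log2 ratio -2.75), 7 of 7 of endothelial-like cells (-3.34) and 9 of 9 of macrophage-like cells (-2.11; -1.304 over 5 genes without the monocyte cluster), all with at least 100 UMIs in 1 mouse. Intervals were apart for all of these except Cp in macrophage-like cells. Under that floor, Serpina3g and Serpina3f were higher in mouse 2 in macrophage-like cells, with overlapping intervals. Free fibroblast RNA would add to other classes no more than the share at which fibroblast markers stood there, at most 4.97% in endothelial-like and 1.28% in macrophage-like cells. The values argue against it for the endothelial-like genes other than metallothioneins, whose excess in mouse 1 was a median of 251% of the fibroblast-like excess (32.3% to 2867%), and for macrophage-like cells, with medians of 13.1% for metallothioneins and 34.1% for the 7 others (0.831% for Cp, within the range of the markers, to 290.3% for Lrg1). The monocyte cluster carried part of the latter: without it, in a check added later, the medians were 13.6% and 4.97%, with lower quartiles of 10.3% and 3.10% against 1.27% at most for the markers. Over the 14 genes of the first form, most of them scarce in endothelial-like cells, the medians were 8.65% and 5.25%, with lower quartiles of 2.10% and 1.48%, so for endothelial-like cells the lower quartile lay within the range of the markers. For Mt1 and Mt2 in endothelial-like cells the median excess of 1.94% lay within the range of the markers, so free RNA may account for it. Neutrophil RNA at the level set by S100a8 fell short of the endothelial-like values by a median of 1051 times over 7 genes, most of them scarce in neutrophils, and by 92.8 times for Lcn2 and 126 times for Lrg1, which neutrophils express; it was not tested in the other classes. Stress during dissociation cannot be told apart from the rest, since the median of the heat shock genes was lower in mouse 2 (-0.88 in endothelial-like, -0.41 in fibroblast-like and -0.56 in macrophage-like cells, with 6, 6 and 5 of 7 genes higher in mouse 1, and Dnajb1 higher in mouse 2 in each class and Hspa1a in macrophage-like cells) while the full immediate early and heat shock list was at -0.03, -0.21 and 0.06; inflammation in mouse 1 is a hypothesis that the design, with 1 group, could not test.

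Clock genes also differed. A different hour of collection may shift early-phase genes such as Nr1d1 and Dbp and late-phase genes such as Cry1 and Nfil3 in opposite directions. Over all listed genes with a UMI in both mice, the early-phase median log2 ratio of mouse 2 over mouse 1 was 0.94 in fibroblast-like cells (6 of 6 higher in mouse 2, 3 with intervals apart), 1.06 in endothelial-like cells (5 of 6, 3 apart) and -0.58 in macrophage-like cells (2 of 5; 1 apart toward mouse 2 and 2 toward mouse 1). The late-phase medians were -0.06, -0.32 and -0.08; Cry1 and Nfil3 were higher in mouse 1 with intervals apart in each class, while Npas2 in fibroblast-like and Arntl in macrophage-like cells were higher in mouse 2. An earlier form with a floor of 100 UMIs left 3 early-phase genes in macrophage-like cells, all higher in mouse 1 (median -0.78), and none in endothelial-like cells. Hour of collection stays open in all 3 classes, since the genes were picked after the mice had been compared and those of macrophage-like cells went both ways. Higher glucocorticoid exposure of mouse 1 stays open: targets not looked at before had a median of -0.34 in fibroblast-like (7 genes), 0.01 in endothelial-like (3) and -0.11 in macrophage-like cells (5) with at least 100 UMIs in 1 mouse, at percentiles 1.81, 45.98 and 19.97 of random lists, where the rule asked for less than 5 in each class. Of the 14 targets listed, 1 was not analysed here. Over all those with a UMI in both mice the medians were -0.14 (13 genes), -0.18 (11) and -0.44 (11). The 7 targets looked at before, Fkbp5 and Zbtb16 among them, were higher in mouse 1 in 7 of 7 genes in each class, but their values were known when the lists were drawn up. Collection times were not used here. Apart from these 2 explanations, no biological explanation was tested.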
